A study of Homo sapiens with 24 samples.

How the data were processed

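RNA from 24 samples of U937 cells was measured on Affymetrix human oligonucleotide expression arrays of 54675 probe sets, 1 array per sample. U937 is an established human monocytic cell line derived from a histiocytic lymphoma. The cells had been differentiated with PMA, a phorbol ester that drives them towards a macrophage-like state, and then left unexposed or exposed to 100 µM hydrogen peroxide for 4 h. After a change of medium they were kept with or without 1 µM curcumin, a polyphenol of turmeric, for 4 or 18 h. The series design text prints both concentrations in mM; the sample protocols and source names give µM, which is used here. Exposure, treatment and time make 8 groups of 3 arrays, numbered as replicates 1 to 3. The labels do not say whether the replicates were separate cultures made on separate days, so every p-value measures only the spread between these samples.

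The deposited values are MAS5 signals, an intensity per probe set on a linear scale, with a smallest value of 0.1; MAS5 is named in the authors' processing notes and its version is not stated. The authors had scaled the arrays: the mean after trimming 2% of the values at each end was 150.02 to 150.025 on all 24. Raw image files and scan dates were not used here. The median signal per array was 30.0 to 44.1, and the number of arrays limits the precision. Control probe sets (62) were left out. Of the other 54613 probe sets, 41091 carried 1 gene symbol, 1801 several and 11721 none in the annotation used here. The annotation gave names only, so no genome positions are reported.

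Signals were analysed as log2 of the signal plus 16. Probe sets with a mean at or above the median of all probe sets (5.59 on this scale, a signal of 32.1) were tested: 27307 probe sets for 12044 genes. One linear model with 8 group means was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided moderated tests), and p-values were adjusted within each of 13 comparisons by the Benjamini-Hochberg method, with a threshold of 0.05. This fit is called the unpaired fit. The same model with the replicate number as a block, also written down beforehand, is called the paired fit. It had 14 residual degrees of freedom against 16 in the unpaired fit. The rules for groups, comparisons, alternatives and named genes were written before the data were examined; applying the naming rule to the paired fit as well was decided after.

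Whether the replicate numbers pair the samples was checked on residuals from the group means. Within a time, the correlation between arrays of the same replicate number was above 0.1 in 36 of 36 pairs (0.30 to 0.74, median 0.59), against a median of -0.29 for different numbers. Between unexposed untreated arrays at 4 h and 18 h it was above 0.1 in 3 of 3 pairs (0.15 to 0.48). The leading principal component held 35.8% of the variance, and the replicate number explained 93.6% of it; the next held 13.4%, of which time explained 86.4%. Over all pairs of conditions between the times it was above 0.1 in 42 of 48 pairs (-0.00513 to 0.61, median 0.48), against a median of -0.18 for different numbers, so the pairing is weaker across the times than within them. The unpaired fit had been written down as the main one; leading with paired values was decided after the counts of both fits had been seen. Counts are given for both fits, and the adjusted p of single genes is from the paired fit unless the unpaired fit is named. Pairs in direction count replicate numbers in which the difference had the sign of the fitted change.

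Two-sided exact sign-flip tests were run on the mean change of each gene list over the 12 replicate pairs of a comparison averaged over the other factors, with adjustment over 42 tests (21 lists and 2 comparisons); the smallest p they can give is 4.88e-04. They were added after the data were seen. The 12 pairs hold only 3 replicate numbers, and the tests flip them independently. Their p-values may therefore be too small where the pairs of a replicate number share a difference. Lists were also tested in every comparison with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data, with adjustment over the lists.

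The 21 lists, 434 distinct genes of which 351 were tested, covered NRF2-driven antioxidant genes, peroxide and superoxide scavenging enzymes, NF-kB target cytokines and regulators, interferon-stimulated genes, heat shock proteins, ATF4 and the unfolded protein response, p53 targets and the DNA damage response, histone deacetylases and sirtuins, the glucocorticoid receptor and its targets, and cholesterol synthesis and uptake. The others were cell division genes, DNA replication genes, immediate early genes, macrophage differentiation markers, metallothioneins, glycolysis and the hypoxia response, oxidative phosphorylation subunits, apoptosis regulators, undifferentiated promonocyte markers, fibroblast and epithelial markers, and lymphoid and erythroid markers. One probe set stood for each gene, the tested one with the highest mean. Of the list genes, 34 had no probe set with a single symbol.

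Named genes were up to 10 per direction with the largest change among those past the threshold (for comparisons of 3 against 3 arrays, only those whose groups do not overlap, which chance alone gives for 10% of genes), or the 3 with the smallest p where none passed, up to 4 members per list, and a few textbook genes fixed beforehand. Genes named outside this rule are marked as chosen after their values were seen.

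Both fits were tested on simulated data with 67 probe sets changed 1.5-fold or 2-fold, or 66 changed 4-fold, among the 27307. For curcumin in unexposed cells at 4 h the unpaired fit recovered 1.49%, 17.9% and 80.3% of these, and the paired fit 19.4%, 58.2% and 100%. For curcumin averaged over conditions the shares were 34.3%, 82.1% and 100% unpaired and 82.1%, 98.5% and 100% paired. For peroxide averaged over conditions they were 44.8%, 85.1% and 100% unpaired and 73.1%, 100% and 100% paired. For peroxide at 4 h they were 1.49%, 29.9% and 90.9% unpaired and 5.97%, 59.7% and 98.5% paired. For 18 h against 4 h they were 0%, 20.9% and 80.3% unpaired and 17.9%, 56.7% and 100% paired. The unpaired fit made 0 false calls in these 5 simulations and the paired fit 3 to 12. The simulated data followed the paired model itself, with a replicate effect equal at both times and noise independent between genes and arrays. The real data need not meet these conditions, so the simulations say little about false calls of the paired fit there.

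Correlations between the 24 arrays were 0.881 to 0.983, and 0 pairs were identical. The arrays of exposed untreated cells at 4 h, replicate 1, and of unexposed untreated cells at 18 h, replicate 1, stood apart. Their BioB spike-in signals were 671.8 and 530.9 against 97.7 to 277.5 on the other 22, and their actin 3'/5' ratios were 1.67 and 1.43 against 0.960 to 1.12. Their 100 brightest probe sets held 13.4% to 13.7% of all signal against 7.80% to 10.9%. Alternatives tried were quantile normalization, centring of arrays, other pseudocounts (1 and 64), no filter or one at the 75th percentile, one probe set per gene, array weights, only the arrays compared, the replicate block, and leaving out each array in turn. A replicate-by-time block and leaving out both arrays that stand apart were added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.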

Results

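Gene expression was measured in PMA-differentiated U937 cells on 24 arrays in 8 groups of 3. The groups combine exposure to hydrogen peroxide or none, curcumin or none, and 4 h or 18 h after the change of medium. The comparisons ask what peroxide did to the cells, what curcumin did in unexposed and in exposed cells, whether curcumin moved expression against the peroxide response, and what changed between the times without any treatment. The depth of an array has no count behind it, and the number of arrays limits the precision.

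After peroxide, the NRF2-driven antioxidant genes were higher as a list in an exact sign-flip test over 12 pairs (adjusted p = 0.0103; camera with an estimated correlation gave an adjusted p of 0.164 unpaired and 0.0454 paired). Several stress genes were higher singly. PMAIP1, which encodes the pro-apoptotic BH3-only protein NOXA, rose by 1.02 on the log2 scale (SE 0.11, 12 of 12 pairs, adjusted p = 2.47e-05), from a mean signal of 1349.7 ± 828 to 2719.5 ± 1713 (SD, n = 12 arrays each). GADD45A, a growth-arrest gene induced by DNA damage, rose by 0.81 (12 of 12 pairs, adjusted p = 6.02e-05), and its relative GADD45B by 0.80 (11 of 12 pairs, adjusted p = 0.00278). TXNRD1, the cytosolic thioredoxin reductase, rose by 0.61 (SE 0.089, 12 of 12 pairs, adjusted p = 0.00185), from 4204 ± 1502 to 6320 ± 1804 (SD, n = 12). GCLM, the modifier subunit of the enzyme that limits glutathione synthesis, rose by 0.57 (SE 0.11, 12 of 12 pairs, adjusted p = 0.0123). DPYSL3, a cytoskeletal protein of the dihydropyrimidinase family, rose by 0.95 (SE 0.14, 11 of 12 pairs, adjusted p = 0.00185), from 84.5 ± 23.1 to 182 ± 60.7 (SD, n = 12). All these values come from the paired fit of peroxide averaged over treatments and times; in the unpaired fit only DPYSL3 passed (adjusted p = 0.0435), and the adjusted p was 0.384 for PMAIP1, 0.401 for GADD45A, 0.914 for GADD45B, 0.208 for TXNRD1 and 0.386 for GCLM.

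The largest rises among the other genes past the threshold were in HCAR3, a receptor for hydroxylated fatty acids (1.20, adjusted p = 0.0349, 9 of 12 pairs, but 0.97 to 4.42 in the 6 pairs at 4 h and -0.44 to 0.62 in the 6 at 18 h, a difference of -2.45 between the times with an adjusted p of 0.0633), and FOSB, a subunit of the transcription factor AP-1 (1.04, adjusted p = 0.0389, 10 of 12 pairs). They were followed by the antisense RNA PAX8-AS1 (0.99), the aldo-keto reductase AKR1C1 (0.95), the membrane protein TM4SF1 (0.92) and INHBA, a subunit of activin A (0.87). The probe set read for AKR1C1 has probes that can match further sequences. TM4SF1 rose by 1.78 to 2.08 in the replicate 1 pairs and by 0.03 to 0.92 in the others. INHBA rose by 0.94 to 2.02 in the replicate 1 pairs and by 0.08 to 1.26 in the others. RSAD2, an interferon-induced antiviral protein, rose by 0.96 with an adjusted p of 0.04995 (11 of 12 pairs), and ISG20, an interferon-stimulated exonuclease, by 0.89 (12 of 12 pairs, adjusted p = 0.0194). The largest falls were in the tyrosine phosphatase PTPN14, which fell by 1.01 (SE 0.14, 12 of 12 pairs, adjusted p = 8.35e-04), the collagen COL10A1 (-0.71), the kinase STK39 (-0.71), haptoglobin HP (-0.67, 9 of 12 pairs) and the myeloid adaptor PRAM1 (-0.64). GPR34, a lysophospholipid receptor of myeloid cells, fell by 0.63 (12 of 12 pairs, adjusted p = 0.00408), and TGFBR1, the type I receptor for TGF-beta, by 0.49 (12 of 12 pairs, adjusted p = 0.0111). IQSEC1, an exchange factor for ARF GTPases, changed by -0.58, TMEM39B by -0.53 and the lipid transfer protein VPS13C by -0.51. VPS13C changed by -0.53 to -1.18 in the pairs at 4 h and by -0.49 to 0.32 at 18 h. IQSEC1 changed by -0.08 to -1.90 at 4 h and by -0.62 to 0.11 at 18 h. Neither VPS13C nor IQSEC1 passed the threshold for a difference between the times. HP changed by -1.46 to -1.76 in the pairs with curcumin at 18 h. Without curcumin at 18 h it changed by -0.03 to -0.98, and in the pairs at 4 h by -1.17 to 0.39. PTPN14 changed by -1.25 to -2.77 in the pairs at 4 h but by -0.09 to -0.68 in those at 18 h. For PTPN14, 3 further tested probe sets had changes of -0.06 to -0.45, each short of the threshold. Of these 20 genes, 14 stayed past the threshold whichever array was left out. For HCAR3, FOSB, RSAD2, INHBA, COL10A1 and PRAM1 the highest adjusted p without 1 array was 0.0795, 0.0851, 0.101, 0.0506, 0.0793 and 0.0716. Leaving out 1 array does not test whether a change rests on 1 replicate number.

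**Figure D1:**
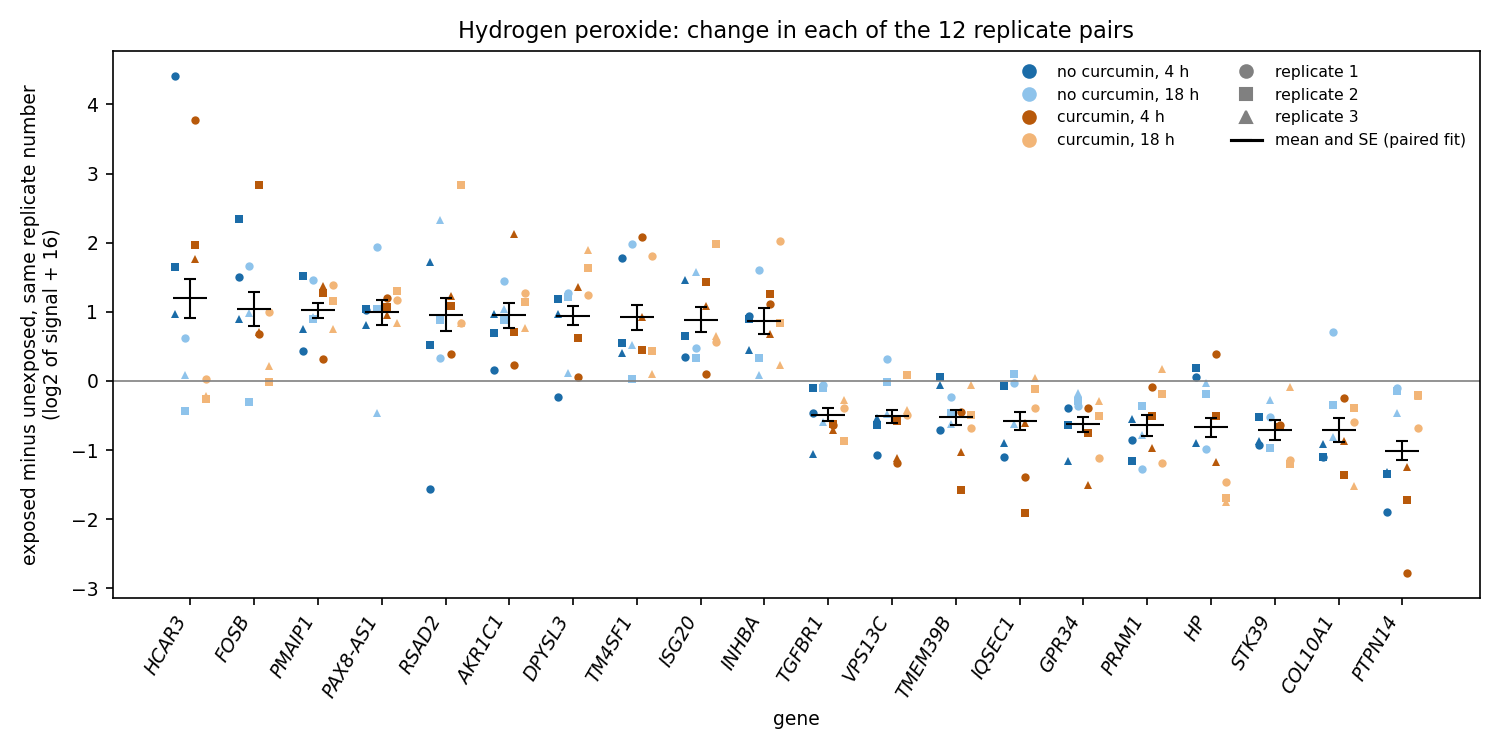
Difference between exposed and unexposed arrays of the same replicate number, in log2 of signal plus 16, for the 10 genes with the largest rise and the 10 with the largest fall after peroxide; each point is 1 of 12 pairs, colour gives treatment and time, marker shape the replicate number, and black bars the mean and its standard error in the paired fit. PMAIP1 lies above 0 and PTPN14 below 0 in 12 of 12 pairs, while HCAR3 lies above 0 and HP below 0 in 9; the HCAR3 pairs at 18 h lie between -0.44 and 0.62.

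The paired fit called 331 probe sets for peroxide averaged over treatments and times, 193 higher and 138 lower (189 genes, 109 higher and 80 lower), by limma with Benjamini-Hochberg adjustment. This fit removes only the mean of each replicate number. Variation of the peroxide effect between the 3 replicate numbers is not fully counted, so the paired p-values and standard errors may be too small. A replicate-by-time block, added after the data were seen, gave 1223. The unpaired fit called 1, DPYSL3 (adjusted p = 0.0435), with 1567 probe sets at an unadjusted p under 0.05 against 3827 in the paired fit and 1365 from chance. Without 1 array the paired count was 171 to 398. It fell by more than 1.5 times without the following arrays: unexposed untreated 4 h replicate 2 (171), exposed untreated 18 h replicate 2 (174), exposed curcumin 18 h replicates 2 (177) and 1 (197), unexposed curcumin 4 h replicate 3 (185), exposed untreated 4 h replicate 3 (202), unexposed untreated 18 h replicate 3 (205) and exposed curcumin 4 h replicate 3 (214). The unpaired call of DPYSL3 stood only without exposed untreated 4 h replicate 1, exposed curcumin 4 h replicate 1, unexposed curcumin 18 h replicate 1 or exposed untreated 18 h replicate 3; without any other single array its adjusted p was above the threshold, up to 0.147. The probe sets called higher had positive changes in 193 of 193 cases in untreated cells at 4 h, 186 at 18 h, 193 with curcumin at 4 h and 191 with curcumin at 18 h, though they were selected on these same arrays.

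Among the lists, the NRF2-driven antioxidant genes, which NRF2 induces under electrophilic and oxidative stress, rose together after peroxide. Their 21 measured members had a mean change of 0.35 (SD 0.20 over 12 pairs), positive in 12 of 12 pairs (exact sign-flip test p = 4.88e-04, the smallest it can give, adjusted p = 0.0103). In the paired fit 7 members were higher and 0 lower, and 13 were higher when adjusted over the list alone. Besides TXNRD1 and GCLM these included SRXN1, which reduces hyperoxidised peroxiredoxins (0.57, adjusted p = 0.00592). The other 14 members averaged 0.20 (11 of 12 pairs positive, exact sign-flip p = 9.77e-04). NQO1, a quinone reductase, had a change of 0.34 (adjusted p = 0.0537, 11 of 12 pairs), and HMOX1, heme oxygenase 1, one of 0.55 (SE 0.25, adjusted p = 0.323, 9 of 12 pairs). The camera adjusted p of the list was 4.55e-14 unpaired, with an adjusted p of 0.164 with an estimated correlation, and 2.14e-16 paired, with 0.0454 as the adjusted p with an estimated correlation. Without any 1 of the 24 arrays the sign-flip adjusted p was up to 0.0205, which adds no support. With 12 of 12 pairs positive, the pairs left are all positive whichever array is left out, which fixes the unadjusted p.

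Of the 18 measured p53 targets and DNA damage genes, 3 were higher in the paired fit, and 3 when adjusted over the list alone: GADD45A, GADD45B and CDKN1A, the cyclin-dependent kinase inhibitor p21 (0.36, adjusted p = 0.0389, up to 0.0860 without 1 array). The list mean was 0.11 (SD 0.099), positive in 12 of 12 pairs (exact sign-flip p = 4.88e-04, adjusted p = 0.0103). Without 1 array the adjusted p was up to 0.0205, which adds no support, since the pairs left are then all positive. GADD45A, GADD45B and CDKN1A carry the list mean. The other 15 averaged 0.01, positive in 5 of 12 pairs (exact sign-flip p = 0.841), and 8 of the 18 members were negative. These 15 were set apart by not being called on the same arrays, so their p-value is biased towards no change. The camera adjusted p of this list was 0.0600 unpaired, with an adjusted p of 0.164 with an estimated correlation, and 0.0194 paired, with 0.0577 as the adjusted p with an estimated correlation.

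Immediate early genes, transcribed within minutes of a stimulus, had 7 members higher and 0 lower of 21 in the paired fit, and 9 when adjusted over the list alone. Besides FOSB, IER5 rose by 0.46 (adjusted p = 0.00574) and FOSL2, an AP-1 subunit, by 0.57 (adjusted p = 0.0125). The list mean was 0.26 (10 of 12 pairs), with an exact sign-flip adjusted p of 0.0752. Leaving out an 18 h array of replicate 2 brought it to 0.0410 in each of the 4 conditions, as did leaving out unexposed untreated 4 h replicate 3. Its camera adjusted p was 5.30e-08, against an adjusted p of 0.164 with an estimated correlation unpaired and 0.0484 paired. The 14 members not called averaged 0.13 (7 of 12 pairs positive, exact sign-flip p = 0.102), a p-value biased towards no change since they were set apart on the same arrays. Of the ATF4 and unfolded protein response list 2 of 23 members were higher in the paired fit, ATF3, a stress-induced transcription factor (0.86, adjusted p = 0.00408), and PPP1R15A, which restores translation after stress (0.43, adjusted p = 0.00836). Adjusted over the list alone 6 were higher and 2 lower, and the list mean of 0.07 had a camera adjusted p of 0.0600 unpaired and 0.0417 paired, with 0.646 as the adjusted p with an estimated correlation.

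Interferon-stimulated genes had a mean change of 0.31 over 24 members, with 3 higher in the paired fit and 8 when adjusted over the list alone; among them IFIT2 changed by 0.71 (8 of 12 pairs, adjusted p = 0.0393, up to 0.0835 without 1 array). The list's camera adjusted p was 0.0358, with an adjusted p of 0.887 with an estimated correlation, and its exact sign-flip adjusted p 0.213. The 6 measured metallothioneins had a mean of 0.29 (camera adjusted p = 8.99e-06, adjusted p = 0.164 with an estimated correlation) and 0 members past the threshold, 5 when adjusted over the list alone. Heat shock proteins averaged 0.17 (camera adjusted p = 0.00706, 0.498 as the adjusted p with an estimated correlation), with 0 of 14 members past the threshold and 2 adjusted over the list alone. NF-kB target genes averaged 0.13 (camera adjusted p = 0.0228, 0.887 as the adjusted p with an estimated correlation): of 24 members 1 was higher, the kinase IRAK2 (0.42, adjusted p = 0.0325, up to 0.0741 without 1 array), and 2 adjusted over the list alone. TNF had a change of 0.25 (adjusted p = 0.651), CXCL8 0.09 (0.625) and IL1B -0.10 (0.809). Glucocorticoid receptor targets averaged 0.10 (camera adjusted p = 0.0228, 0.164 as the adjusted p with an estimated correlation) with 1 member of 16 higher, 2 higher and 1 lower adjusted over the list alone. It was DUSP1, a phosphatase that switches off MAP kinases (0.67, adjusted p = 0.00867); FKBP5 was at -0.04. Paired, the list had 0.0491 as the adjusted p with an estimated correlation, but its mean was positive in 7 of 12 pairs (exact sign-flip adjusted p = 0.224). Apoptosis regulators averaged 0.11 (camera adjusted p = 0.0600 unpaired and 0.00279 paired, with 0.0454 as the adjusted p with an estimated correlation), with PMAIP1 alone of 19 higher and 3 adjusted over the list alone; the exact sign-flip adjusted p was 0.1504.

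Peroxide and superoxide scavenging enzymes did not pass as a group, with a mean of -0.02 over 21 members (camera adjusted p = 0.973). One member passed the threshold in the paired fit: CAT, the catalase that breaks down hydrogen peroxide, fell by 0.31 (12 of 12 pairs, adjusted p = 0.0248, up to 0.0595 without 1 array). The histone deacetylases and sirtuins averaged -0.01 (HDAC2 -0.18, adjusted p = 0.340), cholesterol synthesis and uptake -0.07, cell division genes -0.10, DNA replication genes 0.09, macrophage markers -0.05, glycolysis and hypoxia genes 0.08 and oxidative phosphorylation subunits -0.03. The lists of promonocyte, of fibroblast and epithelial, and of lymphoid and erythroid markers averaged -0.03, 0.07 and -0.02. The camera adjusted p of these 10 lists was 0.0600 to 0.994 unpaired, which does not show that they were unchanged. Paired, glycolysis and hypoxia genes (0.0187) and DNA replication genes (0.0417) passed, with 0.451 and 0.699 as the adjusted p with an estimated correlation, and the other 8 were at 0.329 to 0.998.

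At 4 h without curcumin, TENT5A, a poly(A) polymerase, was the 1 gene past the threshold after peroxide in the paired fit, and none passed in the unpaired fit: it rose by 1.26 (SE 0.20, 3 of 3 pairs, adjusted p = 0.0441), from a mean signal of 622 ± 95.1 to 1527 ± 376 (SD, n = 3). Its adjusted p was 0.147 without unexposed untreated replicate 3, and above the threshold without 4 of the 6 arrays. TXNRD1 and GCLM each had a change of 0.62 at 4 h, and of 0.62 and 0.58 at 18 h. PTPN14 had a change of -1.52 at 4 h (paired adjusted p = 0.0764). At 18 h PMAIP1 had a change of 1.09 (paired adjusted p = 0.198) and GZMB, the protease granzyme B, one of 1.26 (0.192). In the unpaired fit limma called 0 probe sets at both times, with 793 at 4 h and 761 at 18 h at an unadjusted p under 0.05; the paired fit called 1 and 0, with 2374 and 2124. With a replicate-by-time block, added after the data were seen, the calls were 27 and 0.

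Curcumin shifted no single gene past the threshold in any comparison in either fit. Averaged over exposures and times, on the log2 scale, members of the NRF2-driven list, given by list and not by rank, included AKR1C2, an aldo-keto reductase, at 0.64, AKR1C1 at 0.50, TXNRD1 at 0.27 (SE 0.089 paired, 11 of 12 pairs), SRXN1 at 0.27 and SQSTM1, an autophagy receptor, at 0.19. The probe set read for AKR1C1 has probes that can match further sequences. HMOX1 had a value of 0.55 (SE 0.25 paired, 8 of 12 pairs), NQO1 0.21 (11 of 12 pairs), GCLM 0.23 and CXCL8, the chemokine interleukin 8, 0.16 (11 of 12 pairs). TNF was at 0.01, IL1B at 0.07, HDAC2 at 0.03 and FKBP5 at 0.03. With 1 probe set per gene, the smallest p-values in each direction belonged to GLI2 (0.40), LINC00574 (0.83), SSC4D (0.38), RRN3P3 (-0.37), CELF2 (-0.25) and PLXNC1 (-0.37) in the unpaired fit, and to GLI2, GPAT3 (0.27), MINDY3 (0.52), CELF2, PLXNC1 and DEF6 (-0.42, 12 of 12 pairs) in the paired fit. The smallest adjusted p of limma was 0.9999 in the unpaired fit and 0.9994 in the paired fit.

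As a group, the NRF2-driven antioxidant genes had the largest shift with curcumin among the 21 lists, a mean of 0.21 (SD 0.21 over 12 pairs, 11 of 12 pairs positive), with 20 of 21 members positive. The exact sign-flip p was 0.00830, and the adjusted p of 0.0872 did not pass. Without unexposed untreated 4 h replicate 3 or unexposed curcumin 4 h replicate 3, which form the 1 negative pair, it was 0.0137. The camera adjusted p was 3.69e-07, with an adjusted p of 0.981 with an estimated correlation unpaired and 0.240 paired. Over all probe sets 0 members passed; adjusted over the list alone in the paired fit 6 were higher: PGD, TXNRD1, SQSTM1, AKR1C1, AKR1C2 and SRXN1. The ATF4 and unfolded protein response list averaged 0.16 (10 of 12 pairs, exact sign-flip adjusted p = 0.173, camera adjusted p = 3.39e-04, 0.981 as the adjusted p with an estimated correlation). Macrophage markers averaged -0.09 (10 of 12 pairs negative, exact sign-flip adjusted p = 0.139). Only in the paired fit did camera call them (adjusted p = 0.0128), interferon-stimulated genes (-0.11, 0.00225) and heat shock proteins (0.11, 0.0417), with 0.483, 0.835 and 0.835 as the adjusted p with an estimated correlation.

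**Figure D2:**
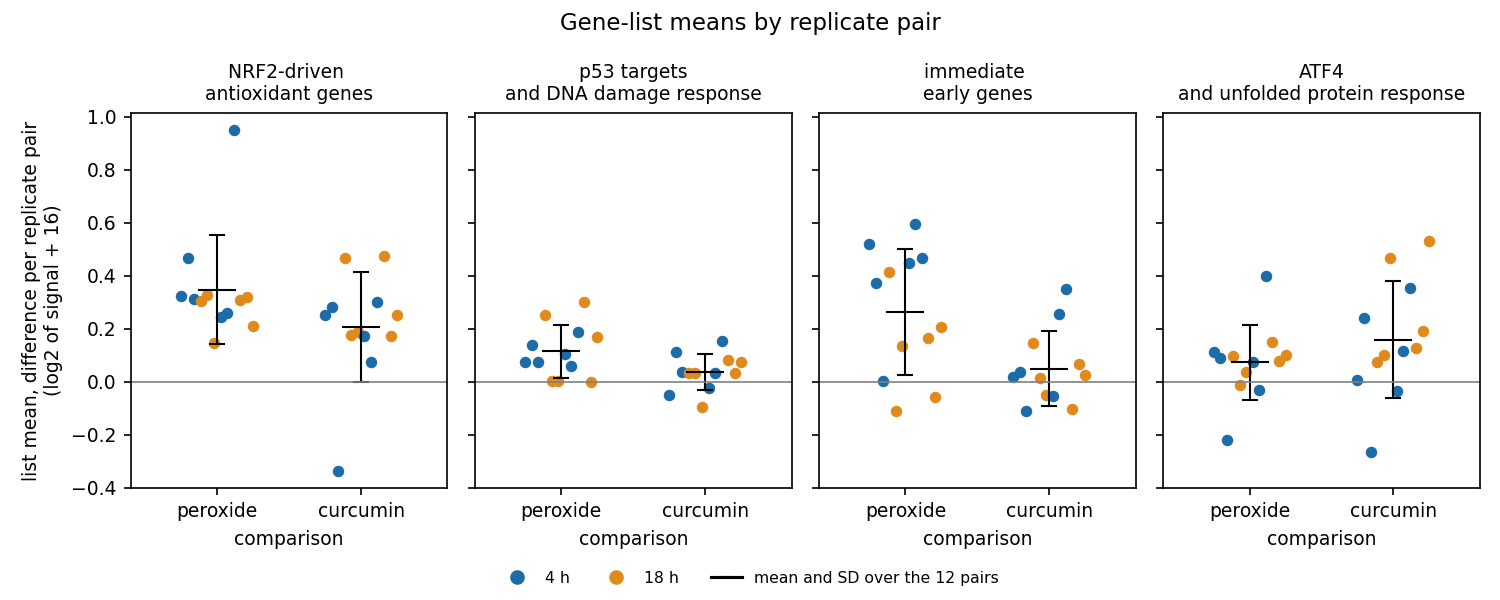
Mean log2 difference of 4 gene lists in each of 12 replicate pairs, for peroxide (exposed minus unexposed) and for curcumin (treated minus untreated), with colour for time and black bars for the mean and SD over the pairs. NRF2-driven genes lie above 0 in 12 of 12 peroxide pairs and 11 of 12 curcumin pairs, with means of 0.35 and 0.21.

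Averaged over conditions, limma called 0 probe sets for curcumin in both fits, with 387 at an unadjusted p under 0.05 unpaired and 1078 paired against 1365 from chance. The median standard error of a change was 0.14 unpaired and 0.11 paired, and 99.8% of the 27307 probe sets had a fitted change below 1/2 of a log2 unit in size. In unexposed cells 0 probe sets were called at 4 h (128 unadjusted, 287 paired) and 0 at 18 h (409 and 903). In exposed cells 0 were called at 4 h (502 and 1109) and 0 at 18 h (226 and 599), although 1 was called in exposed cells at 4 h without exposed untreated 4 h replicate 3. The smallest adjusted p of any probe set in these 4 comparisons was 0.402, in exposed cells at 4 h in the unpaired fit. With 1 probe set per gene, the smallest p was that of HDC, histidine decarboxylase, in unexposed cells at 18 h (-1.27, paired adjusted p = 0.840, 3 of 3 pairs). In unexposed cells at 4 h the genes with the smallest p were NOMO3 (-1.30), HCG22 (-1.14) and KCNH2 (0.92) unpaired and U2AF1 (0.83), MINDY3 (1.12) and KCNH2 paired. In exposed cells they were FLYWCH2 (1.25), CRTAC1 (1.23) and ANKRD20A12P (-0.86) unpaired and LINC00957 (1.09), CRTAC1 and FLYWCH2 paired at 4 h. At 18 h they were KRT9 (-1.05), MXRA8 (-0.78) and DCAF8 (-0.71) unpaired and PLXNC1 (-0.69), DCAF8 and KRT9 paired.

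Whether curcumin acted differently in exposed and unexposed cells was tested as the difference of its effects, and 0 probe sets passed at 4 h (221 at an unadjusted p under 0.05, 500 paired) and 0 at 18 h (283 and 588). With 1 probe set per gene HDC had the smallest p, with a difference of 1.78 at 18 h (paired adjusted p = 0.924). At 4 h the smallest p-values in the unpaired fit were those of HCG22 (1.73), CYP4A11 (1.84) and NOMO3 (1.75). Between the times curcumin's effect differed past the threshold for 0 probe sets (221 unadjusted, 542 paired); TNFRSF12A, the TWEAK receptor, had a difference of 0.54 and ME3, a mitochondrial malic enzyme, one of -0.97.

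Whether curcumin moved genes back along the peroxide response was read from the correlation, across 27307 probe sets, between the curcumin change in exposed cells and the peroxide change without curcumin. It was -0.37 at 4 h and -0.33 at 18 h, but both changes use the exposed untreated arrays with opposite sign, and simulated data without any effect gave -0.50 at both times. With the 2 changes taken from different replicate numbers, so that no array was shared, the mean correlation was 0.0325 at 4 h (-0.0125 to 0.0774 over 6 choices) and 0.00442 at 18 h (-0.0382 to 0.0595). A correlation across genes has no independent replicates. Without an exposed untreated array the shared-array value was -0.65, -0.59 and -0.62 at 4 h and -0.60, -0.51 and -0.50 at 18 h for replicates 1, 2 and 3, against -0.60 in simulated data with 1 such array fewer and no effect. Without exposed curcumin 4 h replicates 1 and 2 it was -0.22 and -0.27, against -0.45 in such simulated data. From the changes that share no array, a reversal of the peroxide response by curcumin was not detected.

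In unexposed untreated cells at 18 h against 4 h, the paired fit called 4 of 17 cell division, 4 of 21 DNA replication and 4 of 16 cholesterol genes lower and 6 of 19 macrophage markers higher. As lists, none of these 4 passed with an estimated correlation (adjusted p = 0.465, 0.465, 0.180 and 0.465). PCLAF, a partner of the replication clamp PCNA, fell by 2.20 on the log2 scale in the paired fit (SE 0.35, 3 of 3 pairs, adjusted p = 0.00198), from a mean signal of 1132 ± 716 to 209.5 ± 99.4 (SD, n = 3). APOBEC3B, a cytidine deaminase, fell by 1.88 (adjusted p = 1.21e-04), and PMAIP1 by 1.62 (adjusted p = 2.53e-04). MMP3, the matrix protease stromelysin 1, rose by 2.13 (SE 0.38, 3 of 3 pairs, adjusted p = 0.00344), from 1039 ± 741 to 4219 ± 2060.1 (SD, n = 3), and S100A8, a calcium-binding protein of myeloid cells, by 1.25 (adjusted p = 0.00344). In the unpaired fit the adjusted p was 0.400 for PCLAF, 0.0531 for APOBEC3B, 0.323 for PMAIP1, 0.450 for MMP3 and 0.207 for S100A8. The paired p-values of this comparison may be too small, for the reason given with its counts. CIRBP, the cold-inducible RNA-binding protein, fell by 1.38 (SE 0.18, adjusted p = 0.00482 unpaired and 1.12e-04 paired), from 1320.5 ± 157 to 496 ± 25.8 (SD, n = 3); another probe set of CIRBP fell by 1.32, and 3 further ones were between -0.17 and 0.02.

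Among genes whose 4 h and 18 h arrays did not overlap, other large falls were in NET1, an exchange factor for RhoA (-1.97), RGS13, a regulator of G-protein signalling (-1.93), and ARRDC3 (-1.84). Next came cyclin E2 CCNE2 (-1.64), LINC01003 (-1.48), C12orf75 (-1.47) and GINS4, a subunit of the replicative helicase complex (-1.45). Other large rises among genes without such overlap were in DHRS13 (1.48), KCTD12 (1.46), PPP1R26 (1.37) and ACVRL1, a receptor of the TGF-beta family (1.37). Next came SLAMF8, a surface receptor of myeloid cells (1.34), KCNJ15 (1.32), PECR (1.27) and the Src-like adaptor SLA (1.19). Of the 20 genes named here in the paired fit, 10 stayed past the threshold without any 1 of the 6 arrays: PCLAF, APOBEC3B, PMAIP1, NET1, RGS13, ARRDC3, LINC01003, MMP3, S100A8 and SLA. Among the other 10 the adjusted p went up to 0.228, for KCTD12 without unexposed untreated 18 h replicate 1.

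All 17 measured cell division genes had negative changes, with a mean of -0.79 (SD 0.70 over 3 pairs). CDK1, the mitotic kinase, fell by 1.77 (adjusted p = 0.0137) and TOP2A, topoisomerase II alpha, by 1.68 (adjusted p = 0.0183); 4 members were lower in the paired fit and 10 when adjusted over the list alone. The list's camera adjusted p was 1.44e-06, with an adjusted p of 0.465 with an estimated correlation. The 21 DNA replication genes averaged -0.71, with 4 lower and 12 adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, fell by 1.72 (adjusted p = 0.00965) and TYMS, thymidylate synthase, by 1.68 (adjusted p = 0.0102). The camera adjusted p was 1.40e-06, with an adjusted p of 0.465 with an estimated correlation. Without unexposed untreated 18 h replicate 1 the adjusted p was 0.102 for CDK1, 0.146 for TOP2A, 0.0897 for RRM2 and 0.0852 for TYMS. The 4 h and 18 h arrays of CDK1, TOP2A, RRM2 and TYMS overlapped, so these genes were named as list members and not by size.

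Cholesterol synthesis and uptake genes had negative changes in 16 of 16 members, with a mean of -0.58, with 4 lower in the paired fit and 11 adjusted over the list alone. INSIG1, which retains the sterol sensor of this pathway in the endoplasmic reticulum, fell by 1.08 (adjusted p = 3.51e-04, up to 0.00653 without 1 array), from 3811 ± 1135 to 1898 ± 868 (SD, n = 3). HMGCS1, the synthase of HMG-CoA, fell by 1.11 (adjusted p = 0.00894, 0.0643 without unexposed untreated 18 h replicate 2) and the sterol carrier STARD4 by 1.08 (adjusted p = 0.00463, up to 0.0399). The list's camera adjusted p was 1.55e-07, with an adjusted p of 0.180 with an estimated correlation. Macrophage differentiation markers averaged 0.46 over 19 members, with 6 higher in the paired fit and 12 higher and 1 lower adjusted over the list alone. The LPS co-receptor CD14 rose by 1.42 (adjusted p = 0.00643, 0.0514 without unexposed untreated 18 h replicate 1), and the gelatinase MMP9 by 0.94 (adjusted p = 0.0256, 0.152 without that array). The 4 h and 18 h arrays of CD14 overlapped. This list's camera adjusted p was 0.0120, with an adjusted p of 0.465 with an estimated correlation. Undifferentiated promonocyte markers averaged -0.47 over 6 members, 5 of them negative (camera adjusted p = 0.0772, 0.465 as the adjusted p with an estimated correlation), and -0.47 to -0.54 in the other 3 conditions.

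Between the times the NF-kB targets averaged 0.12 and metallothioneins 0.03 (camera adjusted p = 0.722 and 0.940). The NRF2-driven genes averaged -0.34 (camera adjusted p = 0.00807, 0.651 as the adjusted p with an estimated correlation), with 1 higher and 5 lower in the paired fit and 3 higher and 8 lower adjusted over the list alone. TXNRD1 fell by 0.88 (adjusted p = 0.00929, 0.0514 without unexposed untreated 18 h replicate 1), while FTL, the ferritin light chain, rose by 0.71 (adjusted p = 0.0414, 0.238 without that array). The ATF4 list averaged -0.45, immediate early genes -0.28 and p53 targets -0.23, with camera adjusted p-values of 4.59e-04, 0.00670 and 0.0499, against 0.465, 0.465 and 0.277 as the adjusted p with an estimated correlation. Oxidative phosphorylation subunits averaged 0.16 and scavenging enzymes 0.15 (camera adjusted p = 0.0167 and 0.0499, against 0.651 and 0.465 as the adjusted p with an estimated correlation). Only in the paired fit did camera also call interferon-stimulated genes (-0.39, adjusted p = 6.39e-04), glycolysis genes (-0.18, 0.0421) and promonocyte markers (0.0348), with 0.422, 0.422 and 0.269 as the adjusted p with an estimated correlation.

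**Figure D3:**
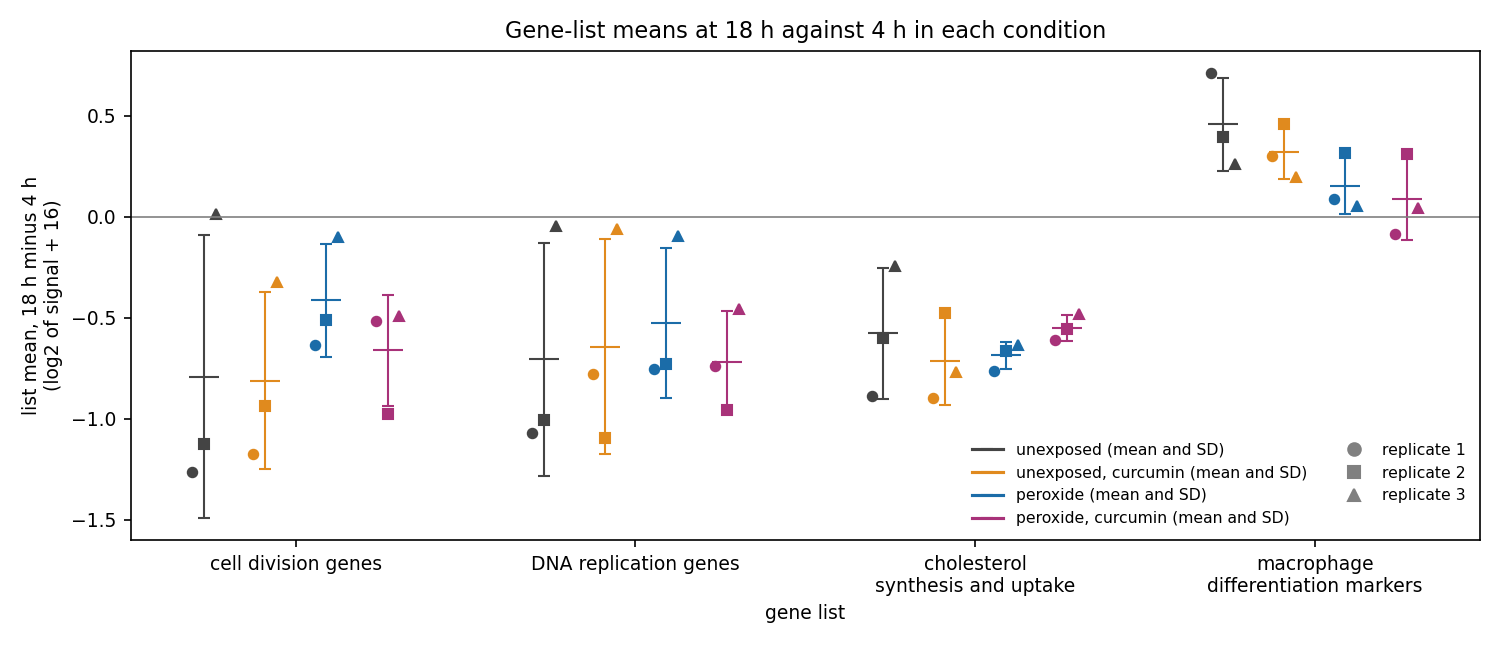
Mean log2 change of 4 gene lists from 4 h to 18 h in each condition; each marker is 1 replicate number (shape), colour gives the condition, and bars give the mean and SD of 3 replicates. The cell division mean is -0.79 in unexposed cells, -0.81 with curcumin, -0.41 after peroxide and -0.66 after peroxide with curcumin; macrophage markers are at 0.46, 0.32, 0.15 and 0.09.

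The paired fit called 889 probe sets between the times, 411 higher and 478 lower (485 genes, 254 higher and 231 lower). It assumes that a replicate number has the same effect at both times. Variation of a replicate number between the times is not fully counted, so the paired p-values and standard errors of this comparison may be too small. Such variation was present: for peroxide averaged, a replicate-by-time block raised the calls from 331 to 1223. The unpaired fit called 2, CIRBP and a probe set of MAP1LC3B, the autophagosome protein LC3B (-0.98, adjusted p = 0.0344), which falls outside the naming rule and was chosen after its value was seen. The paired count was 350, 314 and 325 without unexposed untreated 4 h replicates 1, 2 and 3, and 207 and 365 without unexposed untreated 18 h replicates 1 and 2. The unpaired count was 0 without unexposed untreated 4 h replicate 2, where the adjusted p of CIRBP was 0.0872, 9 without unexposed untreated 18 h replicate 3, and 1 without unexposed untreated 18 h replicate 1 or 4 h replicate 3. The 18 h replicate 1 array is 1 of the arrays with a high spike-in signal and actin 3'/5' ratio.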

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

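Each result in this part comes from a test of the difference between 2 effects (between times, or between exposed and unexposed cells) by limma with Benjamini-Hochberg adjustment. The counts and adjusted p-values of the paired fit without 1 array were chosen only after the result was seen; the swaps in the paired fit and the exchange of differences between the times were chosen after the counts but before their own values. A check of single arrays far from their group was not applied, since it needs at least 4 arrays per group.

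The response to peroxide differed between 18 h and 4 h for several genes, each with an adjusted p in the paired fit beside its value. PARG, which removes poly(ADP-ribose), had a difference of 1.32 (adjusted p = 0.0158), PTPN14 one of 1.42 (0.0482), TUBGCP3, a subunit of the gamma-tubulin complex, 0.82 (0.0482), TMEM161B 0.81 (0.0495) and TMF1, a Golgi protein, 0.73 (0.0245). FOLR1, the folate receptor alpha, had a difference of -1.32 (adjusted p = 3.11e-04), CALR, the chaperone calreticulin, -0.94 (0.0158) and PLEKHA5 -0.92 (0.0333). C6orf62, which falls outside the naming rule and was chosen after its value was seen, had -0.99 (0.00231), and 2 probe sets without a gene name, also outside the rule, had -1.70 (0.0158) and -1.76 (0.00428). Each of the 8 genes named by the rule went the same way in 3 of 3 replicate numbers. In the unpaired fit the adjusted p was under the threshold for C6orf62 (0.0166) and these 2 probe sets (0.0293 and 0.0143), and 0.118 for PARG, 0.603 for PTPN14, 0.780 for TUBGCP3, 0.225 for TMEM161B, 0.327 for TMF1, 0.0779 for FOLR1 and CALR, and 0.208 for PLEKHA5. Other probe sets of CALR were at -0.04 and -0.73, another of FOLR1 at 0.16, and the other 3 of PTPN14 at 0.09 to 0.33. The probe sets read here for CALR, PLEKHA5 and C6orf62 carry the suffix for probes that can match further sequences. PARG, FOLR1 and CALR stayed past the threshold without any 1 array; the adjusted p of the other 5 named by the rule went up to 0.0795 for TMF1, 0.0827 for PLEKHA5, 0.0985 for TUBGCP3, 0.102 for TMEM161B and 0.115 for PTPN14.

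The paired fit called 18 probe sets for this difference, 10 higher and 8 lower, and the unpaired fit 3, all lower; a replicate-by-time block, added after the data were seen, gave 631. Without 1 array the paired count was 7 without exposed untreated 18 h replicate 1 and exposed curcumin 18 h replicate 2, 10 without unexposed untreated 18 h replicate 1, unexposed curcumin 4 h replicate 3 and exposed untreated 18 h replicate 3, and 11 without unexposed untreated 4 h replicate 1, unexposed curcumin 4 h replicates 1 and 2 and exposed curcumin 18 h replicate 1. It was 62 without exposed untreated 4 h replicate 1, 123 without unexposed untreated 18 h replicate 2, 179 without unexposed untreated 4 h replicate 2 and 281 without exposed untreated 4 h replicate 2. The unpaired count was 0 without exposed untreated 18 h replicate 3, 1 without unexposed untreated 4 h replicate 1, exposed untreated 4 h replicate 2, unexposed curcumin 18 h replicate 2 or exposed untreated 18 h replicate 2, and 6 without exposed untreated 4 h replicate 3. With labels redrawn in 100 splits, 4 gave at least 3 calls unpaired, the real one included, with a highest other of 2330; 2 of 100 swaps within replicate pairs gave at least 18 calls paired, with a highest other of 183. The split with 2330 calls parted 4 of the 12 pairs and another with 2141 calls parted 6, against a median of 6 in the other splits. The cause of these large counts was not tested. The redrawn splits and the swaps change exposure itself, so they test for any effect of peroxide and not for a difference between the times. Exchanging the peroxide differences between 4 h and 18 h within replicate and treatment, which keeps the common effect, gave at least 18 calls paired and at least 3 unpaired in 1 of 32 choices, the real one, with a highest other of 1 in each fit. That share is under 0.05, but it treats the 6 differences per time as independent, although they come from 3 replicate numbers. Chance was therefore not excluded.

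Gene lists also differed between the times in their response to peroxide by camera at the preset correlation in the unpaired fit, and each call was lost with an estimated correlation. The mean differences, 18 h minus 4 h, were -0.75 for metallothioneins (6 of 6 members negative, adjusted p = 6.14e-07, 0.402 as the adjusted p with an estimated correlation), -0.31 for NF-kB targets (23 of 24, 0.00642 and 0.907), -0.19 for scavenging enzymes (16 of 21, 0.00417 and 0.434), -0.28 for immediate early genes (17 of 21, 0.0297 and 0.855) and -0.27 for macrophage markers (16 of 19, 0.0357 and 0.640). They were -0.26 for glucocorticoid receptor targets (12 of 16, 0.0359 and 0.434), -0.16 for NRF2-driven genes (14 of 21, 0.0297 and 0.907), -0.13 for oxidative phosphorylation subunits (19 of 26, 0.0359 and 0.907) and -0.12 for glycolysis genes (12 of 19, 0.0498 and 0.855), whose call the paired fit ended (0.0589). Only the paired fit called interferon-stimulated genes (-0.21, adjusted p = 0.0138) and cell division genes (0.26, 0.0283), with 0.663 and 0.639 as the adjusted p with an estimated correlation. The effect of curcumin on cholesterol genes at 18 h was higher by 0.23 in exposed than in unexposed cells (14 of 16 members positive, adjusted p = 0.0202, 0.945 as the adjusted p with an estimated correlation). The effect of curcumin on NRF2-driven genes was higher by 0.16 at 18 h than at 4 h (17 of 21 members positive, adjusted p = 0.0468, 0.961 as the adjusted p with an estimated correlation). For curcumin, camera called NF-kB targets in exposed minus unexposed cells at 4 h only in the paired fit (0.24, adjusted p = 0.00807). The same holds for the ATF4 list at 18 h minus 4 h (0.18, 0.0145). With an estimated correlation their adjusted p was 0.954 and 0.927.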

How the results depend on the processing

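In this part, the replicate-by-time block, the fits without the 2 arrays that stand apart (exposed untreated 4 h and unexposed untreated 18 h, replicate 1), changes taken from different replicate numbers, all alternatives of the paired fit, gene lists without 1 array and the paired list test with an estimated correlation were chosen only after the result was seen. Over 631 results, 14622 alternative values were labelled the same, 473 weaker, 319 stronger, 9 moved and 2 reversed. For genes and lists, weaker and stronger mean that the threshold was lost or gained. For counts they mean a change of more than 1.5 times, or to or from none. A gene short of the threshold that stays short counts as the same. Sign changes in genes short of the threshold (459 of 13791 values of named genes) are not counted as reversed and lie among those labelled the same. For gene lists the replicate block ended 1 camera call (glycolysis genes, peroxide difference between times, adjusted p = 0.0589) and added 24, of which 1, apoptosis regulators after peroxide averaged, also passed with an estimated correlation (0.0454). For counts of probe sets it changed those given below. Where no reason is given, the cause was not tested. Leaving out an array unbalances the replicate numbers, other filters change how many probe sets are tested, and low signals near the background limit what can be called. Fits with only the arrays compared do not exist for the 4 comparisons that use all arrays, and the time comparison has no replicate-by-time block.

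Counts of probe sets moved as follows. With the replicate block they were 1 for peroxide at 4 h, 331 for peroxide averaged, 18 for the peroxide difference between times and 889 for 18 h against 4 h; with the replicate-by-time block 27, 1223 and 631 for the first 3 of these. Curcumin in unexposed cells at 18 h gave 1 with no filter. Peroxide averaged gave 0 with quantile normalization, no filter or the 75th percentile filter, and 9 with array weights. The difference between times gave 0 with one probe set per gene. 18 h against 4 h gave 7 with quantile normalization, 15 with centred arrays, 4 with pseudocount 1, 24 with the 75th percentile filter, 613 with array weights, 0 with only the arrays compared and 1 without both arrays. In the paired fit, peroxide averaged gave 184 with no filter, 508 with the 75th percentile filter, 1223 with the replicate-by-time block and 1 without a block; the difference between times 290 with the 75th percentile filter, 8 with one probe set per gene (fewer probe sets), 5 without both arrays, 631 with the replicate-by-time block and 3 without a block; 18 h against 4 h 509 with no filter, 261 without both arrays and 2 without a block. The correlation of curcumin with the peroxide response reversed to 0.0325 at 4 h and 0.00442 at 18 h with different replicate numbers, since no array was then shared, and was -0.65 at 4 h without both arrays.

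Leaving out 1 array gave counts of 0 to 1 for curcumin in exposed cells at 4 h and for peroxide averaged, 0 to 6 for the difference between times, 0 to 9 for 18 h against 4 h, and 0 to 0 for the other 9 comparisons. In the paired fit it gave 171 to 398, 7 to 281 and 207 to 891 for peroxide averaged, the difference between times and 18 h against 4 h. The correlation was -0.65 to -0.22 at 4 h and -0.60 to -0.26 at 18 h. The arrays behind the changes in these counts and correlations are named with the results.

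Counts of gene lists called by camera were 0 with an estimated correlation for every comparison, and with the replicate block and an estimated correlation 4 for peroxide averaged and 0 for the others. With the replicate block they were 5 for curcumin averaged, 7 for peroxide at 18 h, 12 for peroxide averaged, 1 for the curcumin difference between exposures at 4 h and 2 for the curcumin difference between times. Quantile normalization gave 3 for peroxide at 4 h, 1 at 18 h, 4 averaged, 2 for its difference between times and 0 for the curcumin difference between times. No filter gave 0 for curcumin in unexposed cells at 18 h, 3 and 5 for peroxide at 4 h and 18 h, 3 for its difference between times, and 0 for the curcumin differences between exposures at 18 h and between times. Without both arrays they were 3 for curcumin in exposed cells at 4 h, 6 for curcumin averaged, 10 and 6 for peroxide at 4 h and 18 h, 3 and 5 for the curcumin difference between exposures at 4 h and 18 h, 3 for its difference between times, and 5 for 18 h against 4 h. Leaving out 1 array gave 1 to 7 and 1 to 6 for curcumin in unexposed cells at 4 h and 18 h, 0 to 6 and 2 to 4 in exposed cells, 2 to 6 averaged, 2 to 12 and 3 to 6 for peroxide at 4 h and 18 h, 4 to 11 averaged and 3 to 10 for its difference between times. It gave 0 to 5 for the curcumin difference between exposures at both times, 0 to 3 for its difference between times and 5 to 11 for 18 h against 4 h.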

Other observations

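In this part, the fits without the 2 arrays that stand apart, the exact sign-flip test, the swaps within replicate pairs in the unpaired fit and the pairs parted by each split were chosen only after the result was seen; the other tests of the paired fit, of the overlap and of the gene lists were chosen after the pattern was seen but before their own values.

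The genes that rose after peroxide overlapped with those that were lower at 18 h than at 4 h in unexposed untreated cells. In the paired fit 48 probe sets did both, among them probe sets of 26 genes, of which those given here were chosen after their values were seen: PMAIP1, GADD45A, TXNRD1, SRXN1, SLC7A11, DUSP1, KLF10, PPP1R15A, the transcription factor MAFF, the autophagy protein MAP1LC3B and the deaminase APOBEC3B. The reverse overlap, lowered by peroxide and higher at 18 h, held 17 probe sets against 2.08 for independent lists, while 0 were raised by peroxide and higher at 18 h and 1 was lowered by both. In the other conditions the cholesterol genes also had negative mean changes from 4 h to 18 h (-0.71 ± 0.22 with curcumin, -0.69 ± 0.0679 after peroxide and -0.55 ± 0.0654 after both, SD, n = 3). Metallothioneins had means of -0.87 ± 0.50 after peroxide and -0.79 ± 0.0519 after peroxide with curcumin, against 0.03 ± 0.37 in untreated cells.

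That overlap was weighed against technical explanations. In 10000 draws of lists matched on mean expression the overlap was 5.26 on average and at most 14, against the 48 observed (3.38 for independent lists without matching). The comparisons share the unexposed untreated arrays. These enter the peroxide change with equal weight at both times, so with equal spread they would not by themselves link the comparisons. Equal spread may not hold. Estimated array weights in the paired fit, lower for noisier arrays, were 0.48, 1.04 and 1.05 for these arrays at 18 h and 1.06, 1.80 and 1.06 at 4 h. A larger spread at 18 h would link the comparisons in the direction seen. The peroxide change was also recomputed from the curcumin-treated arrays, which the time comparison does not use. There the 478 probe sets lower at 18 h had a median peroxide change of 0.0954, above the highest of 10000 matched random sets (0.0160), with 346 positive and 132 negative. The direction was thus also seen in arrays that the time comparison does not use, though they share its replicate numbers. Both kinds of draw ignore the correlation between genes, so neither gives a p-value and chance was not excluded. A candidate explanation is that peroxide delays or renews a state that fades with time after the medium change, which no group in the design tests directly.

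The peroxide response in the paired fit was weighed against the arrays and their scaling. Without the 2 arrays that stand apart it held 387 probe sets, of which 252 were among the 331, and after quantile normalization 325, of which 278 were among the 331, which argues against either as the whole cause. Swapping exposure within the replicate pairs gave as many calls in 1 of 100 cases, the real one, with a highest other of 3. These swaps treat the pairs as independent, although they hold only 3 replicate numbers. Chance was therefore not excluded for differences that the pairs of a replicate number share. It stays open whether the peroxide effect belongs to these 3 replicate numbers alone, and the response may in part reflect handling shared by exposed samples, which was not tested here.

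The shift of the NRF2-driven list with curcumin was weighed in the same way. Its mean of 0.21 lay at the 100th percentile of 10000 random lists matched on expression (highest 0.0915, a comparison across genes only), and without the 2 arrays that stand apart it was 0.28. Both argue against a shift tied to signal level and against those arrays as the source. Chance was not excluded by the exact sign-flip test (adjusted p = 0.0872, 0.0137 to 0.164 without 1 array), so the shift may be chance, and a weak NRF2 response to curcumin is a hypothesis only.

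The counts of the other comparisons were set against other splits of the same arrays. For curcumin in each of the 4 conditions and for peroxide at 4 h and 18 h without curcumin, the 10 splits are too few for a share under 0.05; real and highest other counts were 0. For 18 h against 4 h they are also too few, with 2 real calls and 0 as the highest other unpaired (1 of 10 splits as large), and 889 and 0 paired (1 of 4). For peroxide averaged over conditions in the unpaired fit, 2 of 100 splits gave at least the 1 real call, with a highest other of 706. That split parted only 4 of the 12 replicate pairs, against a median of 8, while the real labels part all 12. These splits therefore say little about a count of 1. Swaps within the pairs, which part all 12 as the real labels do, gave 1 call with the real labels and a highest other of 0 in the unpaired fit, but a single call lost without 20 of the 24 arrays carries no conclusion. For curcumin averaged, for its difference between exposures at 4 h and 18 h, and for its difference between times, the real count was 0, which 100 of 100 splits reach by construction, so these splits test nothing. The highest others were 1, 2539, 1 and 2343. The 2 large ones parted 2 of 6 and 6 of 12 pairs, against medians of 4 and 8 in the redrawn splits, and their cause was not tested. For counts of gene lists by camera, chance was not excluded: 24 of 100 swaps gave at least the 2 lists called for curcumin (highest other 4) and 10 of 100 at least the 7 called for peroxide (highest other 11); 51 and 85 of the other swaps gave at least 1 list. For curcumin the lists called were 6 without unexposed curcumin 4 h replicate 3, 5 without exposed curcumin 4 h replicate 3, and 4 without unexposed untreated 4 h replicates 1 or 3 or exposed untreated 4 h replicate 1. For peroxide they were 4 without unexposed untreated 4 h, unexposed curcumin 4 h or unexposed curcumin 18 h replicate 1, or either exposed 18 h replicate 3, and 11 without unexposed untreated 18 h replicates 2 or 3, unexposed curcumin 18 h replicate 2 or unexposed untreated 4 h replicate 3.

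The negative mean change of the cell division list between the times did not rest on the 18 h array that stands apart alone, since the mean over the other 3 conditions was -0.63. Markers of other cell types were at their highest for NKG7 among the lymphoid and erythroid markers, with a mean signal of 1586 at the 96.7th percentile of probe sets, COL1A1 among the fibroblast and epithelial markers (121) and SOX4 among the promonocyte markers (268).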
